A study of Ovis aries with 12 samples.

How the data were processed

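RNA sequencing had been done on the longissimus dorsi, the long muscle of the back, of Tan sheep (Ovis aries) 5 months old. The labels describe 36 sheep on 4 diets with 9 sheep per diet, a pretrial period of 10 days and a trial of 60 days. The diets were a control diet and the same feed with 0.5% succinate (SUC1), 1% succinate (SUC2) or 2% succinate (SUC3), and 3 libraries per diet entered the table, 12 in all. Whether a library held 1 sheep or a pool is not given in the sources used here, so p-values measure the spread between these samples, which may in part be technical.

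The deposited table held whole-number read counts per gene for each library, and these counts were used as deposited. The deposited FPKM values (scaled for gene length and library total) were recomputed from the counts, the gene lengths and the column totals, and the largest relative difference was 3.6e-14. FPKM entered alternative fits only. The aligner and the counting program are not given in the sources used here. Per the submitters' processing notes the builds GRCm38 and mm10 were named, which are mouse assemblies, while the chromosome identifiers and gene descriptions in the deposited table were those of sheep. The build behind the coordinates was not named in the table, so coordinates are printed as the table gave them. Strand use in counting was not stated, so reads of overlapping genes on opposite strands could not be told apart.

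The table listed 21257 genes, of which 5117 had placeholder identifiers and 3569 had no count in any library. Of the GeneIDs, 20874 matched the ARS-UI_Ramb_v3.0 gene table, which was used for names, chromosome labels and a comparison of coordinates. Start and end were identical in both for 8655 genes. This reference gave a symbol to 445 placeholder genes, and the deposited table's own description gave one to 22 more. A further 6 list symbols whose description belonged to several genes, or to none, were left out. No column of per-sample values was left unused. Within each diet, no pair of libraries held identical values or differed by as little as sampling noise.

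Library totals were 15742428 to 18564057 counts (coefficient of variation 4.6%). A floor of 3 counts corresponded to 0.162 to 0.191 CPM (counts scaled to a common library total), which covers counting error only. Genes were kept by the edgeR function filterByExpr with diet as the group, which left 13319 genes. Counts were scaled by TMM, with factors from 0.857 in control replicate 1 to 1.10 in control replicate 2. One quasi-likelihood model (edgeR 4.0.16 in R 4.3.3) was fitted to all 12 libraries with diet as the only factor and 8 residual degrees of freedom. Each succinate diet was compared with control, the diets were compared with each other, and any difference among the 4 diets was tested jointly. A slope over succinate percent was fitted separately. Tests were two-sided with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Adjusted p-values are from edgeR unless another tool is named. Standard errors of log2 fold changes were taken as the absolute log2 fold change over the square root of F. Levels are means of TMM-scaled CPM ± SD over 3 libraries. The biological coefficient of variation was 0.279.

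The design, the alternatives, 28 gene lists and the rule for named genes were fixed before the data were examined. The lists covered slow-twitch fibre, fast-twitch fibre, myogenic regulators, TCA cycle, nuclear respiratory chain, mitochondrial genome, glycolysis and glycogen, fatty acid oxidation, lipid synthesis, adipocyte markers, mitochondrial biogenesis and AMPK, calcineurin and calcium signalling, atrophy and proteolysis, insulin and IGF signalling and hypoxia response. They also covered extracellular matrix and fibroblast markers, immune cell markers, erythroid markers, endothelial markers, smooth muscle and pericyte markers, nerve and Schwann cell markers, immediate early genes, heat shock and chaperones, interferon response, circadian clock, cytosolic ribosomal proteins, cell cycle and unfolded protein response. Lists with at least 3 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2. Camera used a preset correlation of 0.01 and was repeated with an estimated correlation. The rule named, per diet against control, up to 10 genes higher and 10 lower. These had a symbol, an adjusted p under 0.05, a mean of at least 1 CPM in the higher group, no overlap between the groups and the largest change. It added up to 4 members of each list described, by smallest p, and a panel of 12 fibre, metabolic and succinate receptor genes. Where fewer than 5 genes passed, the 5 with the smallest p were named, and for the trend and the joint test up to 10 genes by smallest p. A result for 1 gene that the rule named is not reported here.

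The pipeline was tested on simulated counts drawn from the means and dispersions of the real genes, with 200 genes changed in the SUC2 libraries. Among 13158 genes tested for SUC2 against control, edgeR recovered 22% of genes changed by 1 log2 unit, 69.4% at 1.5, 84% at 2 and 98% at 3, with 12 false calls. DESeq2 recovered 40%, 81.6%, 88% and 98% with 36 false calls, more than edgeR, so its larger counts below may hold more false calls. Limma-trend, with 10542 genes tested, recovered 13.2%, 75%, 95.3% and 97.5% with 9 false calls.

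Alternatives were DESeq2 1.42.0, median-ratio size factors in edgeR, no filter on low counts, a mean of at least 5 CPM, and limma-trend on log2(FPKM + 1). Limma-trend was also run with a pseudocount of 0.1, with median-ratio scaling and with quantile normalization, for genes at 1 FPKM or more in at least 3 libraries. Others were a fit of only the groups compared, a replicate block, stricter and unadjusted thresholds, leaving out each library, leaving out the 20 most abundant genes, and diet rank in place of percent. Removing each library's trend with gene length, leaving out 3 libraries that stood apart together, and comparing the mean of the 3 succinate diets with control were added after seeing the data. Comparisons that share the control libraries were set against 20 simulations of unchanged groups, in which each gene was drawn independently. Scores of gene sets in the closing part are means of log2(CPM + 0.5). Exact permutation tests enumerated all regroupings.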

Results

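The transcriptome of the longissimus dorsi was measured in Tan sheep fed a control diet or the diet with 0.5% (SUC1), 1% (SUC2) or 2% (SUC3) succinate, an intermediate of the TCA cycle. The series asks how dietary succinate relates to muscle fibre characteristics and meat quality. There were 3 libraries per diet. Total counts were 16678596 to 17233737 in control, 15742428 to 17307809 in SUC1, 15870294 to 18564057 in SUC2 and 17085701 to 17465992 in SUC3. A count was present for 15137 to 15617 genes per library. The 13 mitochondrially encoded genes took 7.48% to 15.6% of counts, and the 20 most abundant genes of each library took 30.9% to 38.8%. The share of the latter was 31.7% ± 1.23 in SUC2 and 35.6% ± 3.25 in control (SD, n = 3 each; exact two-sided permutation p = 0.2). With 3 against 3 libraries the smallest such p is 0.1, and none of the library totals, gene numbers or shares reached a p below 0.2. On the first principal component of log2 CPM (19% of variance) the control libraries lay from -44.9 to -27.3 and the succinate libraries from -7.39 to 51.6. SUC2 replicate 2 (55.1) and SUC3 replicate 1 (-52.2) lay apart on the second component (15.8% of variance), and SUC2 replicate 3 (51.6) on the first.

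**Figure D1:**
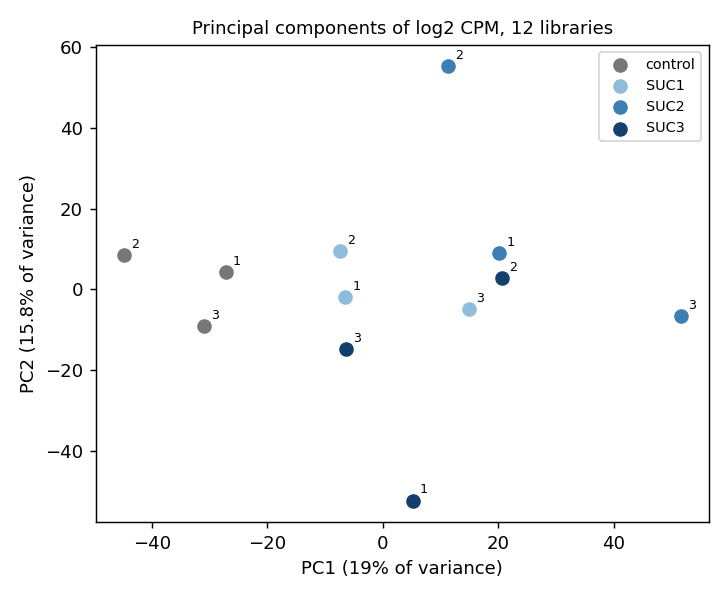
Principal components of log2 CPM for the 12 libraries, with the share of variance on each axis, points coloured by diet and numbered by replicate. The 3 control libraries lie at the low end of the first component, and SUC2 replicate 2 (55.1) and SUC3 replicate 1 (-52.2) are the extremes of the second.

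The 12 panel genes compare fibre type, oxidative and glycolytic metabolism and the succinate receptor directly, and none passed in any diet. MYH1, the myosin heavy chain of fast IIx fibres, was at 49871 ± 6681 CPM in control, 40805 ± 10823 in SUC1, 31800 ± 4143 in SUC2 and 31887 ± 5303 in SUC3 (SD, n = 3). Its log2 fold change was -0.65 ± 0.27 (SE) in SUC2 (adjusted p = 0.220) and -0.65 ± 0.27 in SUC3 (adjusted p = 0.350). MYH7, the slow myosin heavy chain, was at 3741 ± 2939 CPM in control and 5539 ± 406 in SUC3, a difference of 0.57 ± 0.45 (adjusted p = 0.644). The control value of MYH7 was spread by control replicate 1, which had 103411 counts against 35076 and 38060 in the other control libraries. Without control replicate 1, 2 or 3 the SUC3 difference was 1.44, 0.25 or 0.30. In SUC2 the log2 fold change of MYH7 was -0.16 ± 0.45, and it was 0.71, -0.47 or -0.43 without these. MYH2, the heavy chain of IIa fibres, was at 13435 ± 8080 CPM in control and 19140 ± 5522 in SUC3, a difference of 0.51 (adjusted p = 0.630) that was 1.12, 0.24 or 0.33 without control replicate 1, 2 or 3. MYH4 stayed under 16 CPM on average in each diet. Reads of related myosin genes can be shared between copies, which was not tested, so the values of these genes are uncertain. The succinate dehydrogenase subunits SDHA and SDHB had log2 fold changes between -0.14 and 0.11 over the 3 diets, and between -0.26 and 0.25 when single libraries were left out. LDHA, the muscle lactate dehydrogenase, was at -0.56 ± 0.24 in SUC2 (adjusted p = 0.250). PPARGC1A, a coactivator of mitochondrial biogenesis, was at 30.2 ± 16.2 CPM in control and 178 ± 184 in SUC3 (adjusted p = 0.261), with 6837 counts in SUC3 replicate 2 against 2309 and 455 in the other SUC3 libraries; the log2 fold change was 2.56, and 1.32 without SUC3 replicate 2. MSTN, which encodes the growth inhibitor myostatin, was at 51.2 ± 9.03 CPM in control and 18.5 ± 3.98 in SUC3 (log2 fold change -1.47 ± 0.33, adjusted p = 0.145). SUCNR1, the succinate receptor, had 4 to 18 counts per library, with log2 fold changes of 0.51 ± 0.61 in SUC1, 0.56 ± 0.61 in SUC2 and 0.05 ± 0.62 in SUC3. These were -0.11 without SUC1 replicate 2, 0.08 without SUC2 replicate 2 and -0.15 to 0.38 without single SUC3 libraries.

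**Figure D2:**
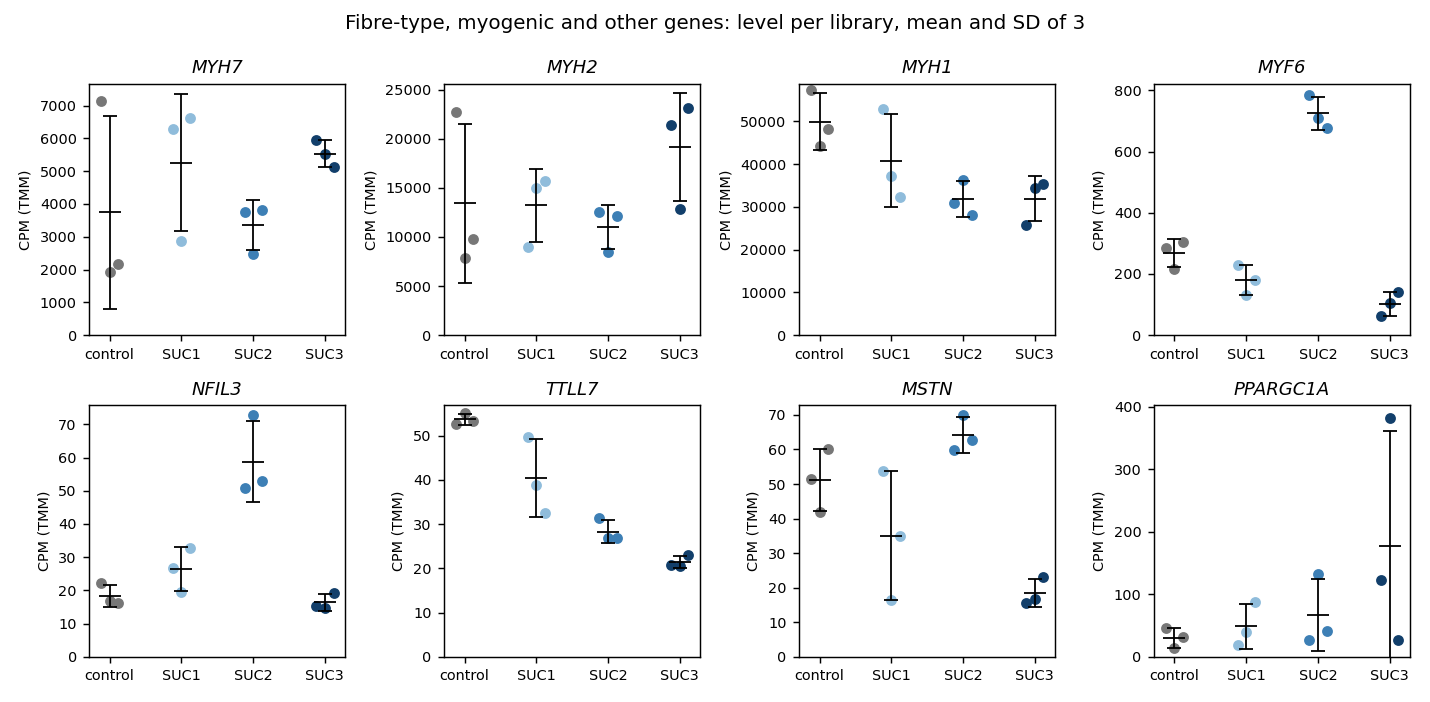
Level in TMM-scaled CPM of 8 genes in each library (points), with the mean and SD of 3 libraries (bars, clipped at 0), by diet. MYF6 averaged 724 CPM in SUC2 against 269 in control and 102 in SUC3, and TTLL7 averaged 53.7 in control and 21.4 in SUC3.

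In SUC1 against control, which asks what the lowest dose changed, 0 of 13319 genes passed by edgeR. At an unadjusted p under 0.05 there were 1014 genes. Without any effect 666 of the 13319 genes would be expected there on average, in this and in every comparison below. DESeq2 called 70 genes and limma-trend 0. The 5 genes with the smallest p, none of which passed, had no overlap between the diets. They were the cytoskeletal genes TPM4, at 83.1 ± 8.32 CPM against 37.8 ± 4.51, and ACTN1, at 28.5 ± 1.65 against 12.8 ± 1.56, with DCLK1, CEP85L and SIK1 (smallest adjusted p = 0.103). TPM4 had a log2 fold change of 1.14 ± 0.16 and SIK1, a salt-inducible kinase, of 2.21 ± 0.41 (adjusted p = 0.225). The count was 7 without SUC3 replicate 2 and 1 without SUC1 replicate 3 or SUC2 replicate 2.

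Of 27 lists tested by camera, 6 were shifted upward in SUC1 at the preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.821. Among the extracellular matrix and fibroblast markers, 28 of 30 members had a positive fold change with a median of 0.63 (adjusted p = 2.69e-11; adjusted p = 0.821 with an estimated correlation). No member passed over all genes and 10 were higher when adjusted over the list alone. COL3A1, a fibrillar collagen, was at 1.46 ± 0.32 and ELN, elastin, at 1.40 ± 0.34. Adipocyte markers had a median of 0.41 with 9 of 12 members positive (adjusted p = 0.0132; adjusted p = 0.821 with an estimated correlation), among them FABP4 at 1.86 ± 0.60 and ADIPOQ at 1.40 ± 0.49. Immediate early genes had a median of 0.28 (adjusted p = 0.00343) and included ATF3 at 3.05 ± 0.77. Slow-twitch fibre genes (adjusted p = 0.0207), cell cycle genes (adjusted p = 0.0197) and immune cell markers (adjusted p = 0.0271) made up the remainder, each at an adjusted p = 0.821 with an estimated correlation, as for immediate early genes. Slow-twitch fibre genes lost the call without control replicate 2, control replicate 3 or SUC1 replicate 3 (adjusted p up to 0.672). Immune markers lost it without control replicate 1, control replicate 2 or SUC1 replicate 2 or with a mean of at least 5 CPM (up to 0.531). Cell cycle genes lost it without control replicate 1 or 2, with a mean of at least 5 CPM or with limma's pseudocount of 0.1 (up to 0.843), and adipocyte markers without control replicate 1 (0.0601).

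SUC2 against control gave the most calls of the 3 diets: 191 genes passed by edgeR, 103 higher and 88 lower, with 2378 at an unadjusted p under 0.05 and 841 called by DESeq2. The genes higher in SUC2 included LMCD1, a LIM-domain transcriptional cofactor, at 1112 ± 255 CPM against 108 ± 115 in control (log2 fold change 3.37 ± 0.67, adjusted p = 0.0332). BAG2, a co-chaperone of HSP70, rose to 413 ± 138 CPM from 73.4 ± 35.3, a 5.63-fold difference (adjusted p = 0.0265). SIK1 rose 5.65-fold to 89.3 ± 19.9 CPM (adjusted p = 0.0213), and SLC25A33, a mitochondrial carrier of pyrimidine nucleotides, rose 6.24-fold from 11.1 ± 0.14 to 69.5 ± 17.3 CPM (adjusted p = 0.0325). PTX3, a soluble pattern-recognition protein, and FOSL1, an AP-1 subunit, rose from below 1 CPM to 7.93 ± 5.93 and 3.42 ± 1.80 CPM. ARMC2, FAM222A, HSPA6 and ARNTL2 completed the genes with the largest increases, the last at 1.10 ± 0.89 CPM. ARNTL2 lay below the floor of 3 counts in every control library (0 to 0.115 CPM), so the size of its increase is uncertain. HSPA6 has near-identical paralogs, so its value is uncertain.

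Among the genes lower in SUC2, DKK2, a secreted modulator of Wnt signalling, fell from 27.7 ± 21.1 to 3.42 ± 2.14 CPM (log2 fold change -3.00 ± 0.60, adjusted p = 0.0332). AQP4, a water channel of the fibre membrane, fell from 30.8 ± 17.0 to 3.93 ± 1.75 CPM. KY, a muscle protein whose loss causes kyphoscoliosis, fell 5.42-fold to 20.8 ± 7.44 CPM (adjusted p = 0.0332). NR1D1, the circadian repressor REV-ERB alpha, fell from 20.9 ± 1.64 to 3.80 ± 3.60 CPM (adjusted p = 0.0472). DUOX1, GOLGA7B, LRRC14B, SLCO5A1 and CILP2 fell 5.38-fold to 8.80-fold. DUOX1 lay below the floor of 3 counts in SUC2 replicates 1 and 3 (0.105 and 0.123 CPM). GOLGA7B was near that floor in SUC2 (0.209 to 0.414 CPM), so the folds of both genes are uncertain. In the table LMCD1 lay on chromosome 19 from 17867007 to 17923710, BAG2 on chromosome 20 from 3189862 to 3199866, and DKK2 on chromosome 6 from 18492309 to 18618733. Of the 191 genes, 190 had no overlap between the 3 SUC2 and the 3 control libraries, against 22.2% of all genes tested and 10% expected by chance. The 191 were chosen by p in these same libraries, so their lack of overlap was largely fixed by the choice and adds no support. The count of calls was 0 without control replicate 2, control replicate 3 or SUC2 replicate 3, 80 without SUC1 replicate 2, 82 without SUC2 replicate 1, 115 without SUC3 replicate 3 and 332 without SUC3 replicate 2. It was also 0 without SUC2 replicates 2 and 3 and SUC3 replicate 1 together, a choice made after seeing the data that leaves SUC2 with 1 library. Limma-trend on unscaled FPKM called 241 genes, 147 of them among the 191, with 75.9% higher, against 53.9% of the 191. With a replicate block 122 genes were called, 50 higher and 72 lower.

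**Figure D3:**
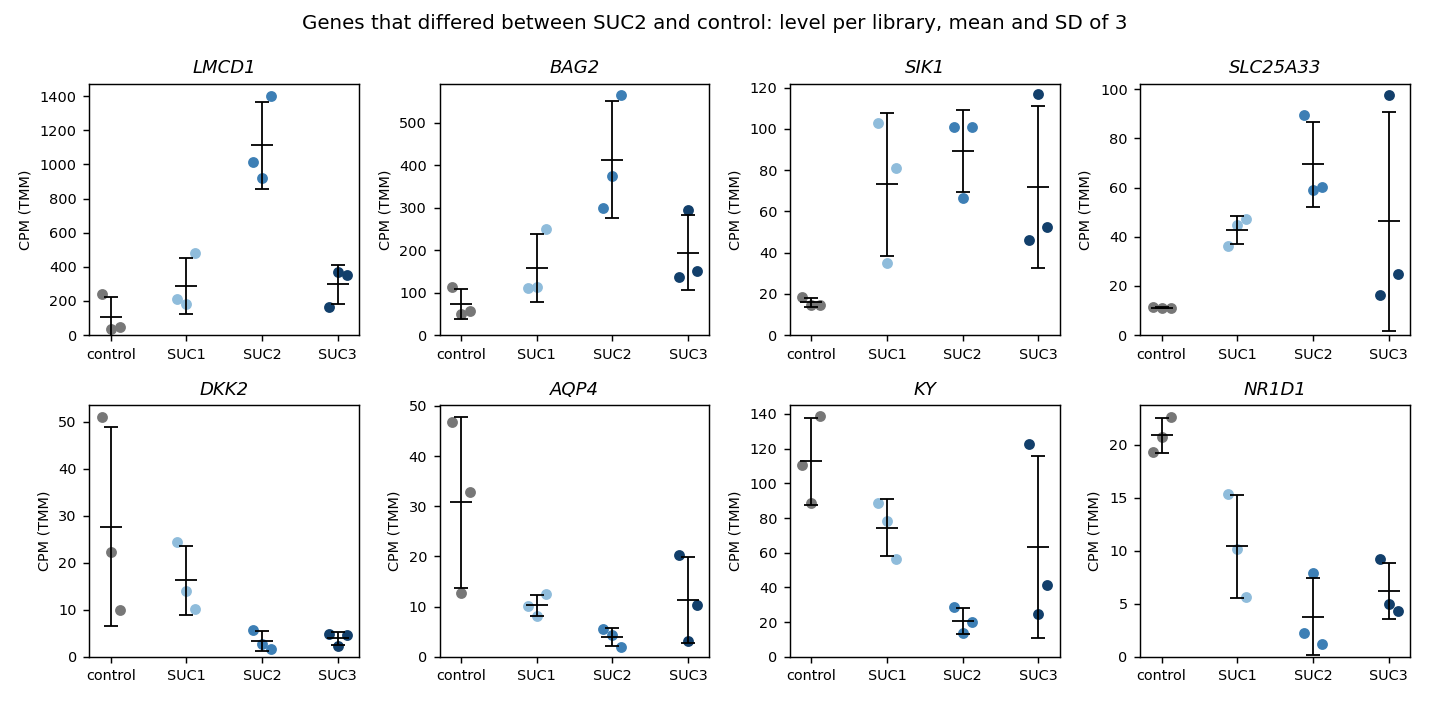
Level in TMM-scaled CPM of 8 genes that differed between SUC2 and control in each library (points), with the mean and SD of 3 libraries (bars, clipped at 0), by diet. Every SUC2 library lies above every control library for LMCD1, BAG2, SIK1 and SLC25A33 and below every control library for DKK2, AQP4, KY and NR1D1. The rule that named these genes required this.

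In SUC2, 9 of 27 lists passed at the preset correlation, 6 upward and 3 downward, and 0 with an estimated correlation (smallest adjusted p = 0.425). All 21 heat shock and chaperone genes had a positive fold change with a median of 0.71 (adjusted p = 2e-08; adjusted p = 0.635 with an estimated correlation). Of these 3 passed over all genes and 11 when adjusted over the list alone. HSPA5, the endoplasmic reticulum chaperone BiP, rose to 183 ± 36.4 from 77.6 ± 2.45 CPM and DNAJA1, a cochaperone, to 209 ± 70.1 from 67.1 ± 22.7. Unfolded protein response genes were shifted upward with a median of 0.28 (adjusted p = 0.0162; adjusted p = 0.425 with an estimated correlation). All 18 immune cell markers were positive with a median of 0.94 (adjusted p = 2e-08; adjusted p = 0.425 with an estimated correlation), and none passed alone over all genes. Among them the macrophage receptor MRC1 was at 1.38 ± 0.33 and CD14 at 1.30 ± 0.34. Extracellular matrix and fibroblast markers (median 0.38, adjusted p = 0.00247), interferon response genes (median 0.48, adjusted p = 0.025) and immediate early genes (median 0.59, adjusted p = 0.0162) were shifted upward, each at an adjusted p = 0.894 with an estimated correlation.

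The 3 downward lists of SUC2 concerned energy metabolism and fast fibres. Of 25 glycolysis and glycogen genes 21 were negative, with a median of -0.43 (adjusted p = 6e-05; adjusted p = 0.808 with an estimated correlation). PHKG1, the catalytic subunit of muscle phosphorylase kinase, fell from 115 ± 9.01 to 62.2 ± 7.22 CPM (adjusted p = 0.0411) and 4 were lower when adjusted over the list alone. All 16 fast-twitch fibre genes were negative with a median of -0.55 and none passed (adjusted p = 0.00296; adjusted p = 0.894 with an estimated correlation). ACTN3, the fast-fibre actinin, was at -0.58 ± 0.23. Of 59 nuclear respiratory chain genes 53 were negative with a median of -0.21 (adjusted p = 0.0437; adjusted p = 0.894 with an estimated correlation). The fast-twitch call ended without control replicate 1 (adjusted p = 0.202), the matrix call without control replicate 2 (0.166), the immediate early call without control replicate 2, control replicate 3 or SUC2 replicate 3 (up to 0.0898) and the interferon call without control replicate 1, SUC2 replicate 1 or SUC2 replicate 3 or with a mean of at least 5 CPM (up to 0.667). The respiratory chain call ended without control replicate 1, SUC2 replicate 2 or 3, or any SUC3 library, or with a replicate block, and its direction turned in 1 of 16 alternatives (adjusted p up to 0.626). For slow-twitch fibre and cell cycle genes, which did not pass, the medians were -0.12 and -0.23 while camera's direction was upward (adjusted p = 0.456 and 0.665).

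Fatty acid genes did not move as lists in SUC2 (fatty acid oxidation, adjusted p = 0.456), while single members passed in both directions. ACSL1, which activates long-chain fatty acids, rose to 1175 ± 336 from 435 ± 155 CPM, and MLYCD, which degrades malonyl-CoA, rose to 67.0 ± 2.52 from 42.7 ± 5.65 CPM. SLC27A1, a fatty acid transporter, fell from 35.4 ± 1.41 to 18.7 ± 0.37 CPM, and PRKAA2, a catalytic subunit of AMPK, fell from 225 ± 26.4 to 121 ± 14.6 CPM. LPIN1, a phosphatidate phosphatase of glycerolipid synthesis, rose to 704 ± 234 from 160 ± 28.1 CPM (adjusted p = 0.0382).

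In SUC3 against control, which asks what the highest dose changed, 1 gene passed by edgeR, with 1658 at an unadjusted p under 0.05, 241 called by DESeq2 and 3 by limma-trend. TTLL7, a tubulin polyglutamylase on chromosome 1 from 60852279 to 61023672, fell from 53.7 ± 1.30 to 21.4 ± 1.30 CPM (log2 fold change -1.33 ± 0.17, adjusted p = 0.0412). DESeq2 called TTLL7 too, while none of the limma-trend calls was this gene (adjusted p = 0.0596), and it did not pass in the pairwise fit (0.0845) or with a replicate block (0.109; up to 0.286 over the alternatives). The next genes did not pass: the growth factor IGF1 was at 22.3 ± 8.20 against 6.48 ± 1.10 CPM, MYH10, a non-muscle myosin, at 76.6 ± 9.77 against 27.3 ± 7.41, ZNF774 at 23.5 ± 3.07 against 10.8 ± 1.63, and MMP14, a membrane-anchored metalloproteinase, at 14.7 ± 2.40 against 5.49 ± 0.34. The count was 0 without control replicate 2 or 3, SUC1 replicate 2, SUC2 replicate 1 or 3, or SUC3 replicate 1 or 2, 3 without SUC1 replicate 3 or SUC2 replicate 2, 9 without SUC3 replicate 3 and 11 without control replicate 1.

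In SUC3, 12 lists passed at the preset correlation, 9 upward and 3 downward, and 0 with an estimated correlation (smallest adjusted p = 0.654). All 16 slow-twitch fibre genes had a positive fold change with a median of 0.52 and none passed alone (adjusted p = 0.000322; adjusted p = 0.654 with an estimated correlation), with MB, myoglobin, at 0.55 ± 0.26. Of 16 fast-twitch fibre genes 14 were negative (median -0.25, adjusted p = 0.01; adjusted p = 0.654 with an estimated correlation), as were 21 of 25 glycolysis and glycogen genes (median -0.24, adjusted p = 0.00173; adjusted p = 0.654 with an estimated correlation). Cytosolic ribosomal protein genes were shifted downward, 71 of 75 negative with a median of -0.25 (adjusted p = 7.29e-05; adjusted p = 0.798 with an estimated correlation). The slow-twitch call ended without control replicate 2 (adjusted p = 0.0705), the glycolysis call without control replicate 1 (0.242), the ribosomal call without SUC3 replicate 1 (0.137) and the fast-twitch call without control replicate 1 or SUC3 replicate 1 or 2 or with quantile-normalized values (up to 0.526).

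Markers of several other cell types were shifted upward in SUC3, but not immune cell markers (7 of 18 positive, median -0.11, adjusted p = 0.716) or, past the threshold, nerve and Schwann cell markers (median 0.36, adjusted p = 0.143). Extracellular matrix and fibroblast markers had a median of 0.68 with 26 of 30 positive (adjusted p = 1.63e-08; adjusted p = 0.654 with an estimated correlation), and 11 were higher when adjusted over the list alone, among them the collagen-degrading MMP2 at 0.96 ± 0.22. All 18 endothelial markers were positive with a median of 0.57 (adjusted p = 8.99e-05), CLDN5 among them at 0.99 ± 0.25. Smooth muscle and pericyte markers (median 0.46, adjusted p = 0.0119), adipocyte markers (median 0.69, adjusted p = 0.0415), lipid synthesis genes (median 0.30, adjusted p = 0.0349), cell cycle genes (median 0.86, adjusted p = 0.00265) and interferon response genes (median 0.55, adjusted p = 8.99e-05) were shifted upward, each at an adjusted p = 0.654 with an estimated correlation, as for endothelial markers. Heat shock and chaperone genes had a median of 0.29 (adjusted p = 0.00297; adjusted p = 0.716 with an estimated correlation). The adipocyte call ended in 8 of 16 alternatives (without control replicate 1 or 3, SUC1 replicate 1 or SUC3 replicate 2 among them, up to 0.581) and the lipid synthesis call in 6 (without control replicate 1 or 2 or SUC3 replicate 1 or 2 among them, up to 0.146). Heat shock genes lost the call without control replicate 2 or 3 (up to 0.117), smooth muscle markers without control replicate 1 or SUC3 replicate 3 (up to 0.0534) and cell cycle genes without SUC3 replicate 3, with a mean of at least 5 CPM or with limma's pseudocount of 0.1, the direction turned in the latter 2 (up to 0.86). Interferon response genes lost it with a mean of at least 5 CPM (0.154).

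**Figure D4:**
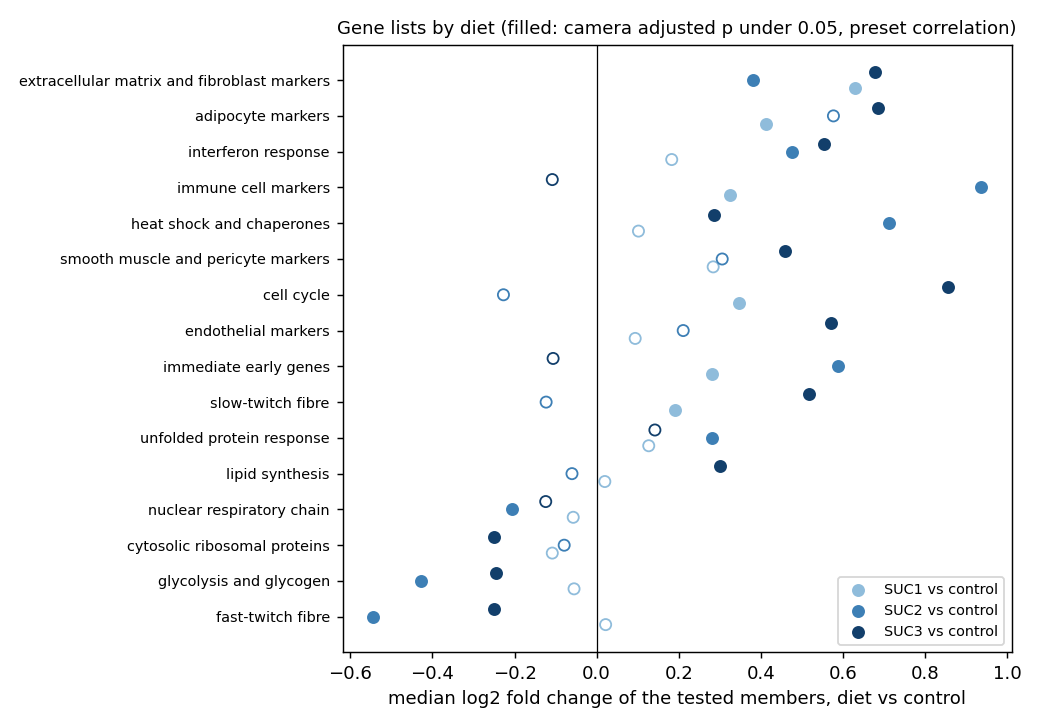
Median log2 fold change of the tested members (horizontal axis) of each list that passed in any of the 3 succinate diets against control. Filled points passed camera at an adjusted p under 0.05 with the preset correlation, and none passed with an estimated correlation. Extracellular matrix markers lie at 0.63, 0.38 and 0.68 in SUC1, SUC2 and SUC3, and fast-twitch fibre genes at 0.02, -0.55 and -0.25.

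The linear trend over succinate percent and the joint test of the 4 diets ask for a dose-related or any diet effect. TTLL7 was the 1 gene called for the trend, at -0.66 ± 0.08 log2 units per percent (adjusted p = 0.0175), with means of 53.7, 40.4, 28.3 and 21.4 CPM from control to SUC3. MMP14 followed at 0.71 ± 0.11 (adjusted p = 0.0517), then MYH10, the ion channel genes KCNH2 and SCN3B, PGRMC2, VASH1, USP9X, PELI3 and KLF12, none of which passed. The trend had 1445 genes at an unadjusted p under 0.05, DESeq2 called 121 and limma-trend 4. TTLL7 was among the former but not the latter (adjusted p = 0.0527), and did not pass with a replicate block (0.0593; up to 0.150 over the alternatives). The count was 0 without control replicate 2 or 3, SUC2 replicate 1, or SUC3 replicate 1 or 2, 2 without control replicate 1 or SUC1 replicate 3, 3 without SUC2 replicate 2 and 12 without SUC3 replicate 3. For the trend, 11 lists passed (8 upward, 3 downward) and 0 with an estimated correlation, where the smallest adjusted p was 0.574. They included slow-twitch fibre genes (adjusted p = 0.00114), endothelial markers (2.69e-05) and nerve and Schwann cell markers (0.0233) upward, and fast-twitch fibre genes (0.00162) and glycolysis and glycogen genes (0.000427) downward. Each of these was at an adjusted p = 0.574 with an estimated correlation. The slow-twitch call ended without control replicate 2 (adjusted p = 0.0711), the fast-twitch call without control replicate 1 or with quantile-normalized values (up to 0.0925) and the nerve call without control replicate 3, SUC1 replicate 3 or SUC3 replicate 1 or 3, with a mean of at least 5 CPM or with limma's pseudocount of 0.1 (up to 0.204).

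The joint test called 3 genes by edgeR, with 1964 at an unadjusted p under 0.05 and 798 called by DESeq2. They were the myogenic regulator MYF6 (adjusted p = 0.0143), NFIL3 (adjusted p = 0.0217) and a gene without a symbol that the table describes as scavenger receptor cysteine-rich type 1 protein M130. With a replicate block 2 genes were called, of which MYF6 alone was among the 3. The M130 gene was singled out after its value was seen, and another gene carries the same description, so its value is uncertain. The count was 0 without SUC2 replicate 3, 1 without control replicate 2, control replicate 3 or SUC3 replicate 1, 5 without SUC2 replicate 1, 6 without SUC1 replicate 1, 21 without SUC3 replicate 3 and 85 without SUC3 replicate 2.

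Between succinate diets, SUC3 against SUC2 gave 2 calls by edgeR (1531 unadjusted, 239 by DESeq2). MYF6, on chromosome 3 from 116764528 to 116765939, was at 724 ± 55.3 CPM in SUC2 and 102 ± 39.9 in SUC3 (log2 fold change -2.83 ± 0.30, adjusted p = 0.00445). NFIL3, a repressor that acts on circadian output genes, was at 58.8 ± 12.1 and 16.4 ± 2.49 CPM (-1.84 ± 0.23, adjusted p = 0.0128). The count was 1, MYF6, without SUC2 replicate 2 (NFIL3 adjusted p = 0.0619) or SUC3 replicate 1 (0.165) or with a replicate block (0.0554), 3 without SUC1 replicate 3, 6 without SUC1 replicate 2, 14 without SUC3 replicate 3 and 66 without SUC3 replicate 2. SUC2 against SUC1 gave 0 calls by edgeR (1142 unadjusted, 53 by DESeq2, 2 by limma-trend), as did SUC3 against SUC1 (974 unadjusted, 69 by DESeq2, 0 by limma-trend). Without SUC1 replicate 3, SUC2 replicate 1 or SUC3 replicate 1 the former count was 1, and the latter was 1 without SUC3 replicate 2 and 2 without SUC3 replicate 3.

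The 3 comparisons with control share the control libraries, so their fold changes correlate without any effect. At an unadjusted p under 0.05, 356 genes were higher and 239 lower in both SUC1 and SUC2, against 79.6 and 56.0 in simulations of unchanged groups and 55.3 and 36.0 for independent lists. For SUC1 and SUC3 these were 281 and 155 genes, against 81.0 and 57.5 simulated and 43.2 and 21.7 for independent lists, and for SUC2 and SUC3 400 and 342, against 78.0 and 56.0 simulated and 93.0 and 56.6 for independent lists. Correlations across genes, which are not independent replicates, were 0.61, 0.59 and 0.57 against 0.504, 0.508 and 0.502 simulated. Covariances were 0.195, 0.165 and 0.203 against 0.087, 0.088 and 0.086 simulated, differences of 0.108, 0.078 and 0.117. The 3 control libraries were too few to be split between the comparisons, so part of the excess overlap may come from the shared controls. The simulations drew each gene independently, so they held no correlation between genes. Deviations that many genes of the control libraries share would raise the overlap beyond them. The excess is therefore no measure of an effect of the diets. TTLL7 was the 1 gene called in both SUC2 and SUC3.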

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

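The tests on clock genes, immediate early genes and markers of other cell types, the bound on abundant genes, the removal of the gene length trend and the fit without 3 libraries together were chosen after the results were seen. The effects of 2 genes differed between the 2% and the 1% diet by the test of that difference itself. MYF6 was lower in SUC3 than in SUC2 by a log2 fold change of -2.83 ± 0.30 (SE, edgeR adjusted p = 0.00445). It was 1.43 ± 0.29 above control in SUC2 (adjusted p = 0.0332) and at -1.40 ± 0.29 in SUC3 (adjusted p = 0.139). NFIL3 was at -1.84 ± 0.23 in SUC3 against SUC2 (adjusted p = 0.0128), at 1.67 ± 0.23 in SUC2 (adjusted p = 0.0213) and at -0.17 ± 0.23 in SUC3 against control (adjusted p = 0.792). Neither gene passed for SUC3 against SUC2 without SUC2 replicates 2 and 3 and SUC3 replicate 1 together (adjusted p = 0.0849 and 0.722), and NFIL3 did not pass without SUC2 replicate 2 (0.0619), without SUC3 replicate 1 (0.165) or with a replicate block (0.0554). The 6 libraries of SUC2 and SUC3 make 10 splits, too few for a share under 0.05. The real split called 2 genes and the highest of the others 0, so 1 split in all called as many.

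The first pattern weighed was the 191 genes called between SUC2 and control. For a few very abundant genes as the cause, the size of the changes was set against the shift they could give. The share of counts left by the 20 most abundant genes could shift the others by at most 0.175 log2 units between a SUC2 and a control library. All 191 genes, 88 of them lower, changed by more than that after 2 SE were taken off (smallest 0.358). Genes chosen by a small p have changes large against their SE, so this outcome was largely fixed by the choice. A shift of at most 0.175 cannot alone give changes of 0.649 or more, the smallest among the 191. Whether it helped some genes to pass was not decided. The test planned first, leaving those 20 genes out, moved too little to decide (189 of the 191 were still called). Removing the gene length trend moved log2 fold changes by at most 0.296 over all genes and 0.09 over the 191. Moves of that size argue against a length trend as the sole source of changes of 0.649 or more. That 186 of the 191 were still called was largely fixed by their choice. With the trend removed 251 genes were called, 139 higher and 112 lower, so the trend did bear on which genes passed. For chance, the 10 splits of the 6 libraries are too few for a share under 0.05; the real split called 191 genes, the highest of the others 0, and 1 split in all called as many. The diet, a difference between the sheep and any difference in collection remain open, and the count rests on single libraries, at 0 without control replicate 2, control replicate 3 or SUC2 replicate 3.

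The second pattern was that clock genes differed between control and succinate libraries. Over 12 clock genes not called in SUC2, the mean of the genes of the ARNTL arm minus that of the NR1D1 arm was 0.845 log2 units higher in the 9 succinate than in the 3 control libraries (SE 0.258, exact two-sided permutation p = 0.0318 over 220 choices). This score measures the pattern itself again, so collection at another time of day cannot be told apart from an effect of the diets. Genes within an arm also went in different directions, as PER1 and PER2 of the NR1D1 arm were above control in SUC1 and SUC2. The time and order of collection are not given in the sources used here. Handling or delay at collection cannot be told apart from no such effect: immediate early genes were 0.507 log2 units higher (SE 0.318, exact two-sided permutation p = 0.15), with too few control libraries to bound it.

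The third pattern was the upward shift of markers of several other cell types. A lower share of muscle fibre RNA would raise all 6 such lists alike. The pair furthest apart differed by 0.887 log2 units in SUC1 (extracellular matrix against nerve markers, SE 0.434, a ratio of 2.04), by 0.704 in SUC2 (immune against smooth muscle markers, SE 0.229, a ratio of 3.08) and by 0.685 in SUC3 (extracellular matrix against immune markers, SE 0.284, a ratio of 2.41). These ratios lay below the bound of 4.12 for 15 pairs, while nerve markers in SUC1 (-0.241, SE 0.288), immune markers in SUC3 (-0.032, SE 0.191) and smooth muscle markers in SUC2 (0.068, SE 0.15), among others, were not above control by more than 1 SE, so a lower fibre share, an influx of single cell types and a change within cells cannot be told apart with 3 libraries per diet. The requirement of more than 1 SE was added after a first version of this test, which asked only for scores above control and which SUC2 met, had been seen.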

How the results depend on the processing

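The removal of the gene length trend and the fits without the 3 libraries that stand apart were chosen after seeing the data. No direction of a called gene turned, and none of the 191 SUC2 genes changed sign in any alternative. The choice of genes largely fixed this outcome, so it is no measure of stability. Of the 191, 190 had no overlap between SUC2 and control, so leaving out a library could hardly turn a sign. Settings that changed only a threshold kept the same fold changes. Of 35 called results for named genes 666 of 951 values kept their side of the threshold and 285 no longer passed. Of 5214 values for 191 uncalled results, 349 passed and 53 changed sign. Median-ratio size factors and leaving out the 20 most abundant genes moved no gene count by over 1.5 times, and the median of all genes moved by less than 0.1 log2 units under each scaling. The causes of the differences below were not tested, except that looser thresholds call more genes and smaller sets of libraries hold less information by construction. Depth limits the precision of genes under 1 CPM, such as SUCNR1, whose SE was 0.61 to 0.62 log2 units.

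Counts are given for SUC1, SUC2 and SUC3 against control unless named. DESeq2 called 70, 841 and 241 genes, 53 for SUC2 against SUC1, 69 for SUC3 against SUC1, 239 for SUC3 against SUC2, 798 for the joint test and 121 for the trend. An unadjusted p under 0.05 gave 1014, 2378 and 1658 genes, then 1142, 974, 1531, 1964 and 1445 in the same order. With an absolute log2 fold change of at least 1 as well it gave 399, 890 and 579, then 350, 359, 528 and, for the trend, 67. An adjusted p with that fold change left 0 genes for the trend. Without a filter on low counts, 3 genes were called in SUC3, 1 for SUC2 against SUC1, 6 for SUC3 against SUC2 and 105 in the joint test. A mean of at least 5 CPM gave 4 in SUC3 and 2 for the trend. Limma-trend on log2(FPKM + 1) gave 3 in SUC3, 2 for SUC2 against SUC1, 5 for SUC3 against SUC2, 28 in the joint test and 4 for the trend. With a pseudocount of 0.1 it gave 2 in SUC3, 1 for SUC2 against SUC1 and 4 for the trend, with 75.1% of its SUC2 calls higher. With median-ratio scaling it gave 0 in SUC3, 4 for SUC3 against SUC2 and 2 for the trend, and with quantile normalization 0 in SUC3, 1 for SUC2 against SUC1 and 5 for SUC3 against SUC2. The pairwise fit gave 8 in SUC1 and 5 for SUC3 against SUC2. Diet rank and removal of the length trend each gave 2 for the trend. Without the 3 libraries that stand apart (SUC2 replicates 2 and 3, SUC3 replicate 1), 1, 0 and 0 genes were called, 1 for SUC2 against SUC1, 1 for SUC3 against SUC2, 1 in the joint test and 0 for the trend. Neither MYF6 nor NFIL3 then passed for SUC3 against SUC2 (adjusted p = 0.0849 and 0.722) or in the joint test, whose 1 gene was none of the 3; SUC2 then had 1 library, assumed to vary like the other groups. The overlap of SUC2 and SUC3 then was 457 genes.

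Same-numbered libraries showed no clear pairing: over 18 pairs from different diets the correlation of their deviations was -0.172 to 0.169, and 5 exceeded 0.1. The median was 0.024 for same-numbered pairs and -0.016 for other pairs. With 3 libraries per diet these values cannot exclude a pairing. With a replicate block SUC2 had 122 calls, 50 higher and 72 lower, 104 of them among the 191, SUC3 had 0, SUC2 against SUC1 had 1, SUC3 against SUC2 had 1 (MYF6), the joint test had 2, of which 1 was among its 3, and the trend had 0.

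With an estimated correlation 0 lists passed in SUC1, 0 in SUC2, 0 in SUC3 and 0 for the trend. Leaving out each library in turn gave 0 to 7 genes in SUC1, 0 to 332 in SUC2, 0 to 11 in SUC3, 0 to 1 for SUC2 against SUC1, 0 to 2 for SUC3 against SUC1, 1 to 66 for SUC3 against SUC2, 0 to 85 in the joint test and 0 to 12 for the trend. Lists ranged from 6 to 12 in SUC1, 6 to 10 in SUC2, 9 to 12 in SUC3 and 8 to 12 for the trend. Genes past an unadjusted p of 0.05 in the same direction ranged from 388 to 714 for SUC1 and SUC2, 298 to 587 for SUC1 and SUC3, and 536 to 900 for SUC2 and SUC3.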

Other observations

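The contrast of the mean of the 3 succinate diets with control, its test on the unadjusted count and the clock scores were chosen after seeing the data. Clock genes moved in both directions in SUC2. NFIL3 rose from 18.4 ± 3.28 to 58.8 ± 12.1 CPM (SD, n = 3; edgeR adjusted p = 0.0213), while NR1D1 and DBP, which ARNTL and CLOCK drive, fell, DBP from 16.6 ± 3.85 to 5.85 ± 2.03 CPM (adjusted p = 0.0411). TEF did not pass at -1.05 ± 0.24 (adjusted p = 0.0516). Of 19 circadian clock genes tested 3 passed over all genes and 10 when adjusted over the list alone, 4 higher and 6 lower, and the list as a whole did not shift (camera adjusted p = 0.448). Over all 15 genes placed in an arm, ARNTL arm minus NR1D1 arm averaged -1.68 log2 units in control and -0.581 in the succinate libraries, a difference of 1.10 (SE 0.249, exact two-sided permutation p = 0.0182), and 8 of 9 succinate libraries lay above every control library. The members of an arm did not all move alike. In the NR1D1 arm, PER1 and PER2 were above control in SUC1 and SUC2, and CIART and BHLHE41 in SUC3. NFIL3, of the ARNTL arm, was below control in SUC3.

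Genes of protein breakdown and of the myogenic programme also changed singly in SUC2. FOXO1, a transcription factor of the atrophy programme, rose from 75.8 ± 8.46 to 362 ± 163 CPM and GABARAPL1, an autophagy gene, from 26.5 ± 2.59 to 68.0 ± 10.3 CPM (edgeR adjusted p = 0.0423 each). Of 25 atrophy and proteolysis genes 2 passed, and the list did not shift (adjusted p = 0.162). MYF6 rose from 269 ± 46.0 to 724 ± 55.3 CPM in SUC2, while MYOD1 was at -1.01 ± 0.44 there and at 1.40 ± 0.43 in SUC3 without passing (adjusted p = 0.250 and 0.232). ABCC9, a subunit of potassium channels, fell from 167 ± 25.1 to 63.0 ± 9.15 CPM and MCM6, a replication licensing factor, rose from 6.35 ± 0.88 to 13.3 ± 1.60 CPM.

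In all, 17 of the 27 lists passed in at least 1 comparison and 10 passed in none. For the latter the smallest adjusted p over the 3 diets and the trend was 0.0763 for atrophy and proteolysis, 0.152 for calcineurin and calcium signalling, 0.199 for insulin and IGF signalling, 0.206 for fatty acid oxidation, 0.237 for hypoxia response, 0.259 for TCA cycle, 0.28 for mitochondrial genome, 0.448 for circadian clock, 0.722 for mitochondrial biogenesis and AMPK and 0.724 for myogenic regulators. Erythroid markers had fewer than 3 tested members and were not tested.

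For the trend, extracellular matrix and fibroblast markers (adjusted p = 1.97e-05), smooth muscle and pericyte markers (0.0267), interferon response genes (2.62e-05) and cell cycle genes (0.0107) were shifted upward, each at an adjusted p = 0.574 with an estimated correlation. Heat shock and chaperone genes were shifted upward (adjusted p = 0.0023; adjusted p = 0.689 with an estimated correlation) and cytosolic ribosomal protein genes downward (adjusted p = 1.97e-05; adjusted p = 0.765 with an estimated correlation). The smooth muscle call ended without control replicate 1 or 2 or SUC3 replicate 1 or 3 (adjusted p up to 0.127). The cell cycle call ended without the same libraries, and also with a mean of at least 5 CPM or limma's pseudocount of 0.1, the direction turned in the latter 2 (up to 0.814). The interferon call ended with a mean of at least 5 CPM (0.0741). The heat shock call ended without control replicate 2 or 3 (up to 0.075) and the ribosomal call without SUC3 replicate 1 (0.0897).

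The mean of the 3 succinate diets against control gave 0 calls by edgeR with 1930 genes at an unadjusted p under 0.05, and a fit of 9 against 3 libraries also gave 0; DESeq2 and limma were not run on it. The genes with the smallest adjusted p of 0.0513 included TTLL7 (-0.89 ± 0.13), TPM4 (0.86 ± 0.14), SIK1 (2.30 ± 0.37), DCLK1 (1.29 ± 0.21), RCSD1 (-1.44 ± 0.23), LIFR (-0.75 ± 0.12) and ROCK2 (1.61 ± 0.26), each without overlap between the 9 succinate and the 3 control libraries. PGRMC2, CERS5 and EDA2R, at the same adjusted p, did overlap. All were ranked by p in these same libraries, so a lack of overlap adds no support. All 100 choices of 3 libraries drawn from 220 call at least 0 genes by construction (the highest called 9), so that count decides nothing on chance. At an unadjusted p under 0.05 the fit of 9 against 3 gave 1736 genes and the highest other choice 1970. Of the 100 choices 4 had as many, the real one included, but the count was taken up after control and succinate libraries were seen to stand apart, so whether chance can be excluded stays open.

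Other groupings of the libraries bear on the remaining counts. For the joint test of the 4 diets, 4 of 60 groupings called at least the 3 genes of the real one and the highest called 15, so chance cannot be excluded; for the trend 3 of 60 called at least 1 gene and the highest 6, with the same reading. The trend's 11 lists were matched by 14 of 60 groupings, the highest with 17, so chance cannot be excluded there either. The 10 splits of 6 libraries are too few for a share under 0.05. SUC1 against control called 0 genes and the highest other split 0, so 10 splits called as many; SUC3 against control called 1 and the highest other 1, in 2 splits in all. SUC2 against SUC1 called 0 and the highest other 3, and SUC3 against SUC1 called 0 and the highest other 1, each with 10 splits as large. At an unadjusted p under 0.05 the real splits against control had 1014, 2378 and 1658 genes in SUC1, SUC2 and SUC3 and the highest others 1082, 1475 and 996. For SUC2 against SUC1, SUC3 against SUC1 and SUC3 against SUC2 the real splits had 1142, 974 and 1531 and the highest others 1164, 881 and 1442. For lists the real splits called 6, 9 and 12 in SUC1, SUC2 and SUC3, and the highest others 15, 13 and 16, with 9, 5 and 2 splits as large. Many lists on other splits may come from correlation between the genes of a list beyond the preset 0.01 or from a structure of the libraries other than diet. On the real groups 0 lists passed with an estimated correlation in any diet or for the trend, so every list call depends on the preset value. The other splits were not run with an estimated correlation, and which of these explanations applies to them was not tested.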
